A study of Homo sapiens with 6 samples.

How the data were processed

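The samples were 6 full-thickness reconstructed human skin tissues (EpiDerm FT), a commercial model in which keratinocytes form a layered epidermis on a dermal layer that holds fibroblasts. Per the labels' protocols, tissues were equilibrated for 24 h, then 25 µl of zingerone at 50 µg/ml (group Z) or of water (group CTL) was applied to the surface, and RNA was collected 24 h later from 3 tissues per group. RNA was purified on silica columns, labelled with biotin and hybridised to Affymetrix Human Gene ST strips, which carry probes against most annotated human genes. The 6 arrays lay on 3 strips, each with 1 CTL and 1 Z array, and the sample codes number the replicates by strip. All 6 titles say replicate 1, so the strip number was used as the replicate number. The protocol describes treatment in triplicate, and if arrays shared a tissue every SD, SE and p would measure the array step alone. All tissues came from the same commercial product, and nothing in the labels ties them to separate donors, so p-values measure the spread between these tissues, which may be technical. Per the same protocols, the zingerone stock was made up in DMSO (20 mg/ml) before dilution with water, which leaves 0.25% DMSO by dilution, while the control is described as water. By that description the solvent differed together with the treatment.

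The deposited table holds log2 values per probe set, and the authors made them with RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes. The RMA version, the array definition and the settings are not given in the sources used here. The medians of the arrays were 2.47, 2.46 and 2.57 in CTL 1, 2 and 3 and 2.48, 2.47 and 2.56 in Z 1, 2 and 3. Both arrays of strip 3 thus had the higher medians. For arrays, the number of tissues limits the precision, and the table gives no detection call, so a low value cannot be separated from background. No value column was left unused.

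The table has 53617 probe sets. A probe annotation table paired 23871 of them with 1 gene symbol and 1842 with several symbols, and 27904 were unnamed here. No gene was named from a probe set with several symbols. Symbols were updated through the RefSeq gene table of assembly GRCh38.p14, used for names only: 22569 probe sets matched by gene identifier and 565 by an older symbol, 4 kept the symbol of the annotation table, and 655 symbols changed. Of 22357 distinct symbols, 663 had several probe sets, and the brightest one stood for the gene. Genes with a mean above the median of all probe sets (log2 value 2.49) were tested, which left 14868 genes.

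Z was compared with CTL by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are log2 Z minus CTL, given with limma's SE. Gene lists on matrix, proteases, cytokine responses, stress responses, epidermal differentiation and cell types were fixed before the data were examined, as were the tests and the alternatives. The 40 lists with 5 or more tested members were tested by limma's camera with its preset correlation of 0.01 between genes, adjusted over the lists. The melanocyte markers had 3 tested members and were not tested. Each list is described by the mean log2 difference over its tested members. Camera was repeated with the correlation estimated from the arrays. Fry, which asks whether the members of a list move on balance in a single direction without setting them against other genes, was run as a further alternative. Exact symbols were required, so members that share a probe set with another gene are missing from their lists.

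The genes named were set by a rule written before the data were examined. It takes, leaving out sex-linked markers and small noncoding or unnamed features, the 12 higher and the 12 lower genes with the smallest limma p that moved the same way on all 3 strips. It adds the members of each list that passed the test (at most 4) or else the 2 with the smallest p, and the 4 members with the highest level in the matrix metalloproteinase, IL-17A target and core matrisome lists. Any gene named outside it is said to be chosen after its values were seen.

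The strip numbers pair the arrays. After subtraction of the group means, the deviations of the CTL and Z arrays of the same strip correlated at 0.19, 0.15 and 0.44 across genes on strips 1, 2 and 3, and each array correlated best with the array of its own strip. Genes are not independent replicates. The fit without the strip was the main design, and a fit with the strip as a block was an alternative. Other alternatives were a random strip effect, no filter on level or a filter at the 75th percentile (log2 value 3.84), median centring, quantile normalization again, the mean of a gene's probe sets, all probe sets, a trended and robust prior, array weights, other thresholds, camera on ranks, each array left out and each strip left out. No pair of arrays held identical values.

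The procedure was tested on simulated data for this comparison. For 14868 genes with the measured means and residual SDs and 200 changed genes, limma recovered 57.6% of 2-fold changes and 11.8% of 1.5-fold changes, with 2.4 false calls among 71.8 calls on average over 20 runs. Among 40 simulated lists of 30 independent genes, camera with the preset correlation called a list shifted by 0.15 in 19 of 20 runs, and camera with an estimated correlation called it in 0. In lists without any effect whose members were correlated at 0.124, the median estimate from the real lists, the preset correlation called 4.9 of 40 lists on average, between 0 and 10 per run, and the estimated correlation 0. Since the estimates of the real lists ran from -0.17 to 0.53, a further 200 runs without an effect, added after the data were seen, gave each of 40 lists the size and estimate of a real list, with negative estimates set to 0 and no shared members. There the preset correlation called 7.7 lists on average, between 1 and 19 per run, and the estimated correlation 0. Figures were drawn with matplotlib 3.10.9, and tables were joined in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.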

Results

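Expression was measured in 6 reconstructed human skin tissues 24 h after zingerone at 50 µg/ml (Z, n = 3) or water (CTL, n = 3) was applied to the surface. Zingerone is a phenolic compound of ginger. The series title names its analog acetyl zingerone, matrisome synthesis, matrix metalloproteinases (MMPs) and IL-17A target genes, and the experiment analysed here applied zingerone itself. The question is which genes and gene groups differ between zingerone and water in this tissue. Values are log2 RMA values, and differences are Z minus CTL with limma's SE. Treatments were applied in triplicate per the protocol, but all 6 array titles say replicate 1, so n = 3 counts arrays taken to be separate tissues. By dilution of its stock the zingerone solution also held 0.25% DMSO, while the control is described as water.

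The 12 higher and 12 lower genes with the smallest p among protein-coding or otherwise named genes that moved the same way on all 3 strips differed by less than 2-fold and none passed the adjusted threshold. Of the 12 higher genes, ENDOU, an endoribonuclease, was at 5.11 ± 0.01 in Z and 4.39 ± 0.15 in CTL (SD, n = 3 each), a difference of 0.72 (SE 0.13) or 1.65-fold. S100A7A, a calcium-binding protein of the psoriasin family, differed by 0.82 (SE 0.15), and its close relative S100A7 may share probes with it. SYK, a non-receptor tyrosine kinase, differed by 0.71, EFNA5, a ligand of Eph receptors, by 0.64, and P2RX7, an ATP-gated ion channel, by 0.61. IL18BP, which binds and neutralises IL-18, differed by 0.54. SH3RF2 (0.80), AHNAK2 (0.65), SLC47A2, an organic cation exporter (0.64), TP53INP2, an autophagy factor (0.59), ZNF502 (0.55) and MRRF, a mitochondrial ribosome recycling factor (0.68), completed the 12 genes. IL18BP, P2RX7 and ZNF502 were low in CTL, at 2.84, 2.93 and 2.29.

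Of the 12 lower genes, CTSL, the lysosomal protease cathepsin L, was at 6.21 ± 0.0022 in Z and 6.77 ± 0.02 in CTL (SD, n = 3 each), a difference of -0.56 (SE 0.11). CEMIP, a hyaluronan-binding protein needed for hyaluronan breakdown, differed by -0.98 (SE 0.22), and TMEM158 by -0.91 (SE 0.15). The neutrophil chemokine CXCL5 differed by -0.76, TNFRSF11B, the decoy receptor osteoprotegerin, by -0.69, NENF, a secreted neurotrophic factor, by -0.70, and EFEMP2, the elastic fibre protein fibulin-4, by -0.55. COLEC12, a scavenger receptor, differed by -0.58, GNPNAT1, an enzyme of amino sugar synthesis, by -0.59, and TMEM150C, low at 2.63 in Z, by -0.48. The remaining entries were the pseudogenes POU5F1P4 (-0.97) and RPSAP52 (-0.74), whose probes may also read their parent genes.

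**Figure D1:**
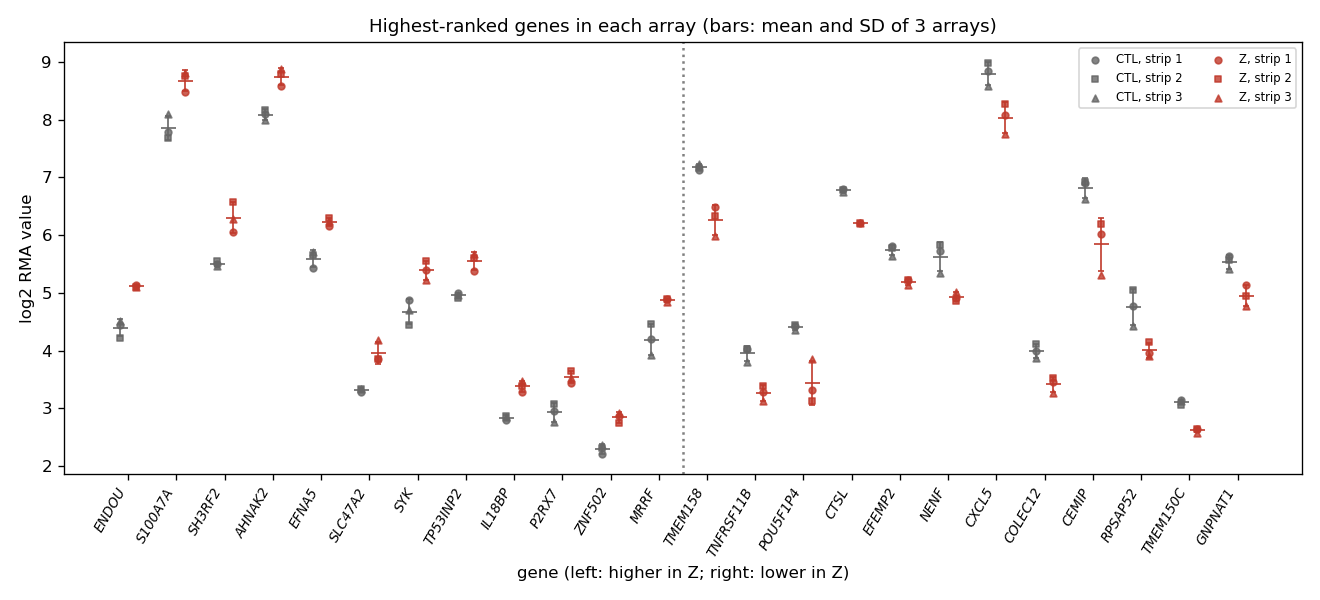
Log2 RMA value (y axis) of the 12 higher and 12 lower genes named by rank of p (x axis), with each array as a point whose shape gives its strip, and bars for the mean and SD of 3 arrays per group. The means of CTSL are 6.77 in CTL and 6.21 in Z, and none of the 24 genes passed the adjusted threshold.

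Limma called 0 of 14868 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.551. At an unadjusted p under 0.05 there were 1225 genes (8.24%, where chance gives 5%), 707 higher and 518 lower in Z. That split was 57.7% higher, and quantile normalization again gave 667 higher and 739 lower, or 47.4% higher. Differences over all genes ran from -1.33 to 1.36, with 234 genes beyond 1.5-fold and 12 beyond 2-fold, against a median SE of 0.15. The values of the groups did not overlap for 2159 genes (14.5%, where chance gives 10% if arrays of a strip are unrelated). Arrays of the same strip did correlate, so that 10% is only a guide. In all, 5498 genes (37.0%, where chance gives 25%) moved the same way on all 3 strips. With the strip as a block, limma called 0 genes (smallest adjusted p 0.27) and 1926 had an unadjusted p under 0.05. There were 1607 such genes without CTL 3, 760 without Z 2 and 515 without both arrays of strip 2. Without CTL 3, 1 gene was called, PRR9, a proline-rich gene of the epidermal differentiation region, chosen here after its values were seen. PRR9 was at 6.20, 6.12 and 4.02 in CTL 1, 2 and 3 and at 3.93, 4.35 and 4.08 in Z 1, 2 and 3, a difference of -1.33 (SE 0.50, limma adjusted p = 0.576) with all arrays and -2.04 (SE 0.16, limma adjusted p = 0.0244) without CTL 3. CTL 3 had the lowest array weight in limma (0.555, with 0.877 for Z 2 and 1.67 for CTL 1), and its Spearman correlation with Z 3, on the same strip, was the highest of any pair (0.961). Whether the CTL 3 tissue matches the other controls is not known, which limits every value that moves without it.

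Extracellular matrix genes, the subject named by the title, went both ways, somewhat more of them lower than higher in Z. EFEMP2 (-0.55, SE 0.12), IGFBP6, which binds insulin-like growth factors (-0.66, SE 0.16), CEMIP (-0.98) and HAS2, a hyaluronan synthase (-0.76, SE 0.20), were lower. Of the 4 core matrisome genes at the highest level, FN1, fibronectin, differed by 0.28 (SE 0.13), COL1A1, a chain of type I collagen, by 0.06 (SE 0.13), THBS1, thrombospondin, by -0.09 (SE 0.14) and LUM, the proteoglycan lumican, by -0.23 (SE 0.16), and COL1A1 was at -0.01 without CTL 3. Of 130 tested core matrisome genes, 57 were higher and 73 lower, with a mean difference of -0.06 and a median of -0.03. In simulation, camera with an estimated correlation called a list shifted by 0.15 in 0 of 20 runs. A high p from it thus does not argue against a shift of that size. The core matrisome list did not pass camera in limma (adjusted p = 0.0626, or 0.786 with an estimated correlation). Its mean was -0.13, -0.09 and 0.03 on strips 1, 2 and 3, and its level was 5.35, 5.33 and 5.14 in CTL 1, 2 and 3 and 5.22, 5.24 and 5.17 in Z 1, 2 and 3. Without CTL 3 it was -0.13 (limma adjusted p = 0.00428), and without Z 2 it was -0.08 (limma adjusted p = 0.0398). Without strip 3 it was -0.11 (limma adjusted p = 0.00241), while it was -0.023 without CTL 1, -0.03 without CTL 2 and -0.03 without strip 1. No core matrisome gene passed limma over all genes and none passed adjusted over the list alone (0 of 130).

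Within the matrix, genes for collagen folding and crosslinking fell as a group in camera, with 25 of 31 lower, a mean of -0.12 and an adjusted p of 0.00495 in limma, or adjusted p = 0.752 with an estimated correlation. PLOD2, a lysyl hydroxylase that prepares collagen for crosslinks, differed by -0.42 (SE 0.13), and MIA3, which exports procollagen from the endoplasmic reticulum, by 0.36 (SE 0.13). The mean was -0.16, -0.19 and -0.02 on strips 1, 2 and 3. Camera in limma no longer called the list without CTL 1 (adjusted p = 0.0852), strip 1 (adjusted p = 0.101) or strip 2 (adjusted p = 0.0577). Its means ran from -0.19 without CTL 3 to -0.08 without CTL 1. Extracellular matrix glycoproteins also fell in camera, 40 of 65 lower with a mean of -0.08 (limma adjusted p = 0.0405, adjusted p = 0.787 with an estimated correlation), and the mean was -0.18, -0.11 and 0.06 on the 3 strips. That call was lost in limma without CTL 1, CTL 2, Z 1, Z 3, strip 1 or strip 2 (adjusted p of 0.362, 0.209, 0.196, 0.0714, 0.685 and 0.0606) and on ranks (adjusted p = 0.0862). Its means ran from -0.17 without CTL 3 to -0.03 without strip 1. Collagens, with COL4A6 at 0.24 and COL8A1, low at 2.45 in Z, at -0.23, were not called with all arrays (19 of 34 lower, mean -0.04, limma adjusted p = 0.329). They were called without strip 3 (-0.11, limma adjusted p = 0.046). Their adjusted p in limma was 0.786 with all arrays and an estimated correlation, and their mean was 0.0052 without strip 1. Proteoglycans and hyaluronan genes, 17 of 31 higher, were not called (limma adjusted p = 0.568), and their mean of -0.05 and median of 0.05 had opposite signs. That mean ran from -0.07 without Z 1 to -0.0012 without Z 3. TGF-beta response genes, 21 of 28 lower with ID2 at -0.32 and BHLHE40 at 0.25, had an adjusted p of 0.181 in limma, and were called without CTL 3 (-0.15, adjusted p = 0.0218), against an adjusted p of 0.833 with all arrays and an estimated correlation. Their mean was -0.06 with all arrays and -0.0070 without Z 3.

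Of 15 tested MMPs, 11 were lower in Z. MMP3, the stromelysin that cleaves several matrix proteins, differed by -0.82 (SE 0.24) and was lower on each strip, by -0.34, -0.87 and -1.25. MMP1, the interstitial collagenase and the MMP at the highest level, was at 10.40 ± 0.18 in Z and 10.82 ± 0.03 in CTL (SD, n = 3 each), a difference of -0.42 (SE 0.13). MMP14, a membrane-bound activator of other MMPs, differed by -0.16 (SE 0.12) and MMP2, a gelatinase, by -0.02 (SE 0.12), with MMP2 at 0.02 without CTL 1 and 0.04 without Z 1. The list mean was -0.12 (limma adjusted p = 0.106, or 0.752 with an estimated correlation), at -0.07, -0.21 and -0.07 on strips 1, 2 and 3, and it ran from -0.17 without Z 1 to -0.07 without strip 2. The median over members was -0.08, at -0.08, -0.15 and 0.0084 on strips 1, 2 and 3. No MMP passed limma over all genes, and 0 passed adjusted over the list alone. Among genes above the 75th percentile of level the list mean was -0.24 (limma adjusted p = 0.0151). Matrix protease inhibitors were lower for 14 of 19 genes, with the secreted inhibitors SLPI at -0.58 (SE 0.17) and CST6 at -0.60 (SE 0.20), and were not called with all arrays (limma adjusted p = 0.0626). They were called above the 75th percentile of level (-0.15, limma adjusted p = 0.0151) and without Z 2 (-0.17, adjusted p = 0.0232). ADAM and ADAMTS proteases, with ADAMTS6 at -0.82 and ADAMTS17, low at 2.35 in CTL, at 0.33, were not called with all arrays (limma adjusted p = 0.144). They were called without Z 2 (-0.14, limma adjusted p = 0.0232). For the inhibitors and for these proteases the adjusted p in limma was 0.752 with all arrays and an estimated correlation. The inhibitor mean was -0.13 with all arrays and -0.07 without Z 3, and that of the proteases -0.09 with all arrays and -0.05 without CTL 2.

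IL-17A target genes of keratinocytes went both ways, 27 higher and 26 lower of 53 tested. S100A7A differed by 0.82 and CXCL5 by -0.76, and these 2 genes passed limma adjusted over the list alone (adjusted p of 0.0293 and 0.0463) while 0 passed over all genes. The 4 targets at the highest level were PI3, the protease inhibitor elafin (0.14, SE 0.13), S100A7 (-0.03, SE 0.12), S100A8, a subunit of calprotectin (0.01, SE 0.12), and SERPINB3, a serpin of squamous epithelium (0.18, SE 0.12). Leaving out CTL 3 or Z 2 turned the sign of S100A7 (0.0036 and 0.04), and leaving out CTL 2 or Z 1 turned that of S100A8 (-0.03 and -0.02). The list mean was -0.05 and its median 0.01, of opposite sign, with means of -0.09, -0.01 and -0.05 on strips 1, 2 and 3. Without Z 3 the mean was -0.0061, and without CTL 3 or Z 2 it was -0.09. Camera in limma did not call it (adjusted p = 0.695, or 0.828 with an estimated correlation).

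**Figure D2:**
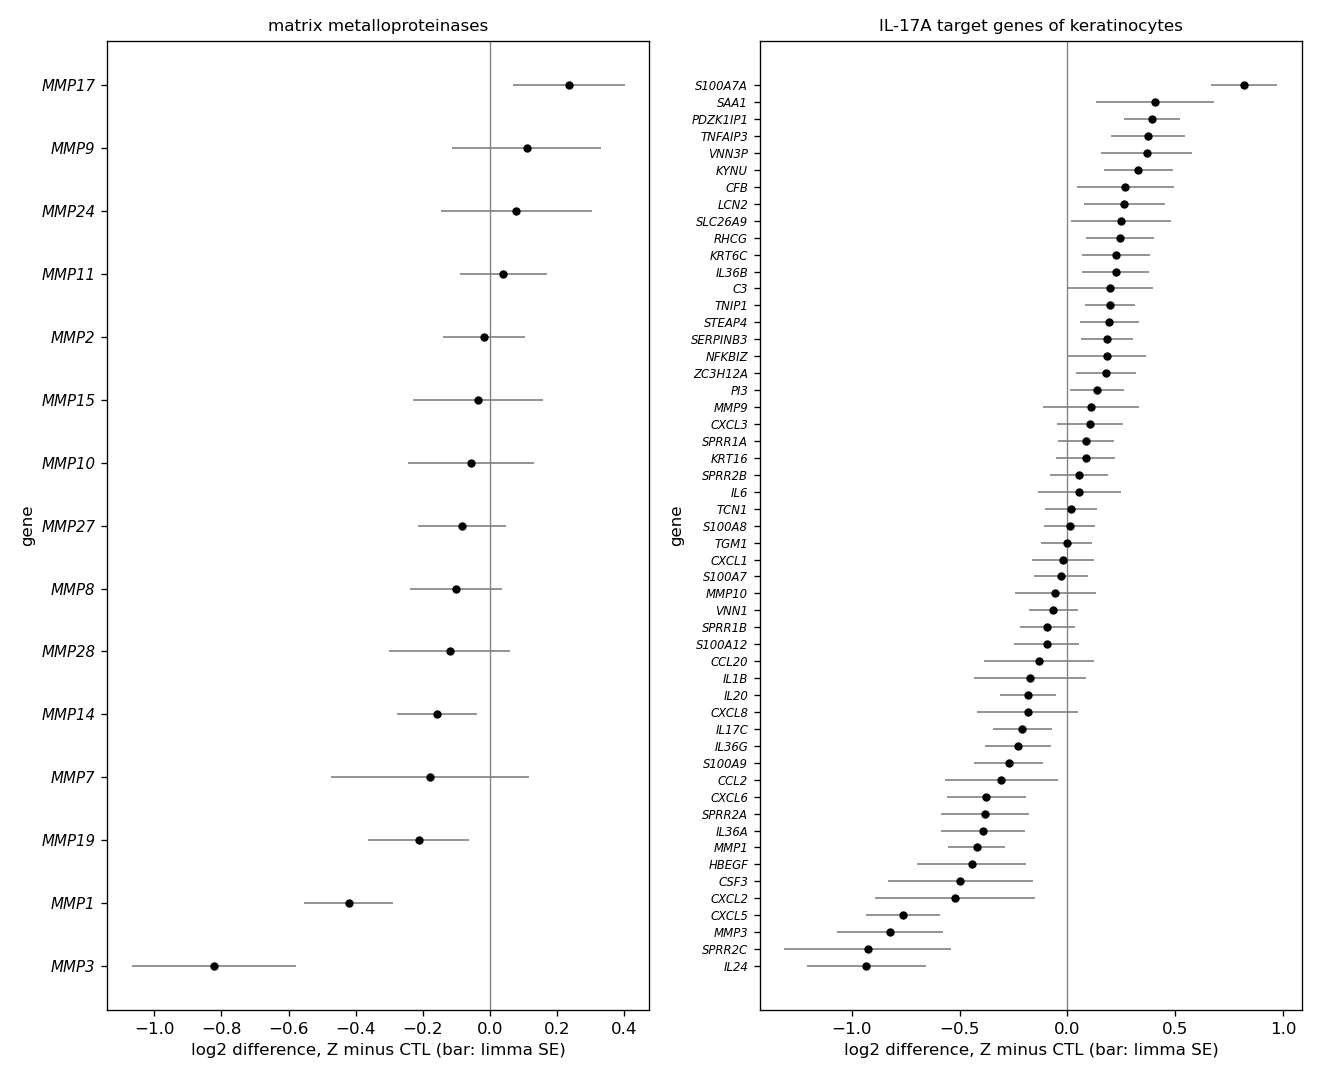
Log2 difference Z minus CTL (x axis) with limma's SE as bars for each tested matrix metalloproteinase (left) and IL-17A target gene of keratinocytes (right), genes on the y axis. MMP3 (-0.82) and MMP1 (-0.42) lie farthest to the left among the MMPs, and IL-17A targets spread from IL24 (-0.93) to S100A7A (0.82).

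Cytokines and chemokines were lower for 24 of 37 genes with a mean of -0.12, and IL24, a cytokine of the IL-10 family, differed by -0.93 (SE 0.27). Camera in limma gave an adjusted p of 0.0626, and 0.0439 with the strip as a block, the only list that the block added, while the adjusted p was 0.752 with an estimated correlation. The mean was -0.18, -0.05 and -0.15 on strips 1, 2 and 3, and the list was called in limma without Z 2 (adjusted p = 0.00795) or strip 2 (adjusted p = 0.0163), and above the 75th percentile of level (-0.15, adjusted p = 0.0265). The mean ran from -0.19 without Z 2 to -0.06 without Z 3. NF-kB response genes, 18 higher and 18 lower, included CD83 at -0.54 and IER3 at -0.62 and were not called with all arrays (limma adjusted p = 0.821), with a mean of -0.02 and a median of 0.0075, but were without Z 2 (-0.15, adjusted p = 0.0256). Their adjusted p in limma with all arrays and an estimated correlation was 0.95, and their mean was 0.10 without Z 3. Type I interferon response genes rose as a group in camera, 37 of 45 higher with a mean of 0.12 (limma adjusted p = 0.0205, adjusted p = 0.752 with an estimated correlation). IRF9, a subunit of the interferon-activated transcription factor, differed by 0.40 (SE 0.13) and OAS2, an antiviral enzyme, by 0.38 (SE 0.13). The interferon mean was 0.14, 0.14 and 0.07 on strips 1, 2 and 3. The call was lost in limma without CTL 3 (0.06, adjusted p = 0.112), Z 1 (0.08, adjusted p = 0.147), strip 1 (adjusted p = 0.126) or strip 2 (adjusted p = 0.0606). The mean was 0.19 without Z 3.

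Both of the lists that follow, of epidermal barrier genes, rose in camera. For barrier lipid synthesis, 33 of 41 genes were higher with a mean of 0.19 (limma adjusted p = 6.31e-05, adjusted p = 0.752 with an estimated correlation). Among them were the lipoxygenase ALOX15B (0.45, SE 0.13) and CYP4F22, which makes the omega-hydroxylated fatty acids of barrier ceramides (0.43, SE 0.13). For the cornified envelope and late differentiation, 42 of 55 were higher with a mean of 0.14 (limma adjusted p = 0.000344, adjusted p = 0.752 with an estimated correlation), with CASP14, a protease of cornifying cells, at 0.57 (SE 0.13) and PPL, periplakin, at 0.47 (SE 0.14). The barrier lipid mean was 0.05, 0.38 and 0.15 on strips 1, 2 and 3, and the cornified envelope mean was 0.04, 0.28 and 0.12. Without Z 2 they were 0.10 and 0.08, and without both arrays of strip 2 they were 0.10 and 0.08 and no longer called in limma (adjusted p of 0.0577 and 0.0606).

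Cholesterol synthesis genes, 20 of 23 higher, rose in camera with a mean of 0.11 (limma adjusted p = 0.0307, adjusted p = 0.752 with an estimated correlation), with SREBF2, the transcription factor of the pathway, at 0.31 and DHCR7, its last enzyme, at 0.28. Cell junction genes, 22 of 35 higher, rose with a mean of 0.09 (limma adjusted p = 0.0314, adjusted p = 0.752 with an estimated correlation), with the desmosomal cadherin DSC3 at 0.32 and E-cadherin, CDH1, at 0.29. The cholesterol mean was 0.12, 0.13 and 0.09 on strips 1, 2 and 3, and the junction mean 0.09, 0.03 and 0.15. The cholesterol call was lost in limma without CTL 2, CTL 3, Z 1 or any strip (adjusted p from 0.0535 to 0.161). The junction call was lost without any array but Z 2 or without any strip (adjusted p from 0.0577 to 0.184). Without CTL 3 their means were 0.06 and 0.05, and without Z 3 the cholesterol mean was 0.18. Keratins (14 of 21 higher, limma adjusted p = 0.144) included KRT2, a keratin of the upper epidermis, at 0.64 and KRT13, a keratin of mucosal epithelium, at -0.60, and were called without the filter on level (0.11, adjusted p = 0.037). Basal keratinocyte genes (15 of 24 higher, limma adjusted p = 0.164) included EGFR at 0.37 (SE 0.11) and KRT5 at 0.35 (SE 0.11), and were called without Z 2 (0.11, adjusted p = 0.0165). For both lists the adjusted p in limma was 0.752 with all arrays and an estimated correlation. The keratin mean was 0.12 with all arrays and 0.05 without strip 2, and the basal mean 0.07 with all arrays and 0.0047 without Z 1. The late cornified envelope cluster was not called with all arrays (10 of 16 lower, mean -0.11, limma adjusted p = 0.252), with LCE3E at -0.78 (SE 0.21) and LCE3D at -0.31. These are close relatives whose probes may be shared. The cluster's mean was -0.30, 0.27 and -0.29 on strips 1, 2 and 3. It was called lower in limma without Z 2 (-0.30, adjusted p = 5.79e-06) and without strip 2 (-0.29, adjusted p = 1.05e-05), and was at 0.01 without Z 3. Its estimated correlation of 0.528 was the highest of the 40 lists, and with all arrays and an estimated correlation its adjusted p in limma was 0.844.

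Of the cell type markers tested, those of keratinocytes and fibroblasts were called by camera with the preset correlation and the others were not. Keratinocyte markers, 10 of 13 higher, rose in camera with a mean of 0.13 (limma adjusted p = 0.0298, adjusted p = 0.752 with an estimated correlation), at 0.14, 0.12 and 0.13 on strips 1, 2 and 3. Fibroblast markers, 14 of 19 lower, fell with a mean of -0.14 (limma adjusted p = 0.0218, adjusted p = 0.752 with an estimated correlation), at -0.25, -0.26 and 0.08 on the 3 strips, with FBLN2, fibulin-2, at -0.49 (SE 0.13) and S100A4 at -0.49 (SE 0.19). The fibroblast marker level was 6.37, 6.37 and 6.13 in CTL 1, 2 and 3 and 6.12, 6.11 and 6.21 in Z 1, 2 and 3, so CTL 3 lay among the Z arrays. The keratinocyte call was lost in limma without CTL 1, CTL 2, Z 1, Z 3 or any strip (adjusted p from 0.0577 to 0.154). The fibroblast call was lost without CTL 1, CTL 2, Z 1, strip 1 or strip 2 (adjusted p from 0.0852 to 0.251), with means from -0.26 without strip 3 to -0.09 without strip 2. Endothelial markers (3 of 6 higher, FLT1 -0.31, ERG 0.26), immune cell markers (7 of 11 lower, ITGAM 0.63, CD68 -0.26) and nerve and muscle markers (6 of 10 higher, DES -0.29, TNNT3 -0.24) were not called (limma adjusted p of 0.769, 0.439 and 0.821). The endothelial mean ran from -0.04 without strip 2 to -0.0019 without CTL 1, and the immune mean from -0.08 without CTL 1 to -0.02 without CTL 3. The nerve and muscle mean of -0.01 and median of 0.08 had opposite signs.

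**Figure D3:**
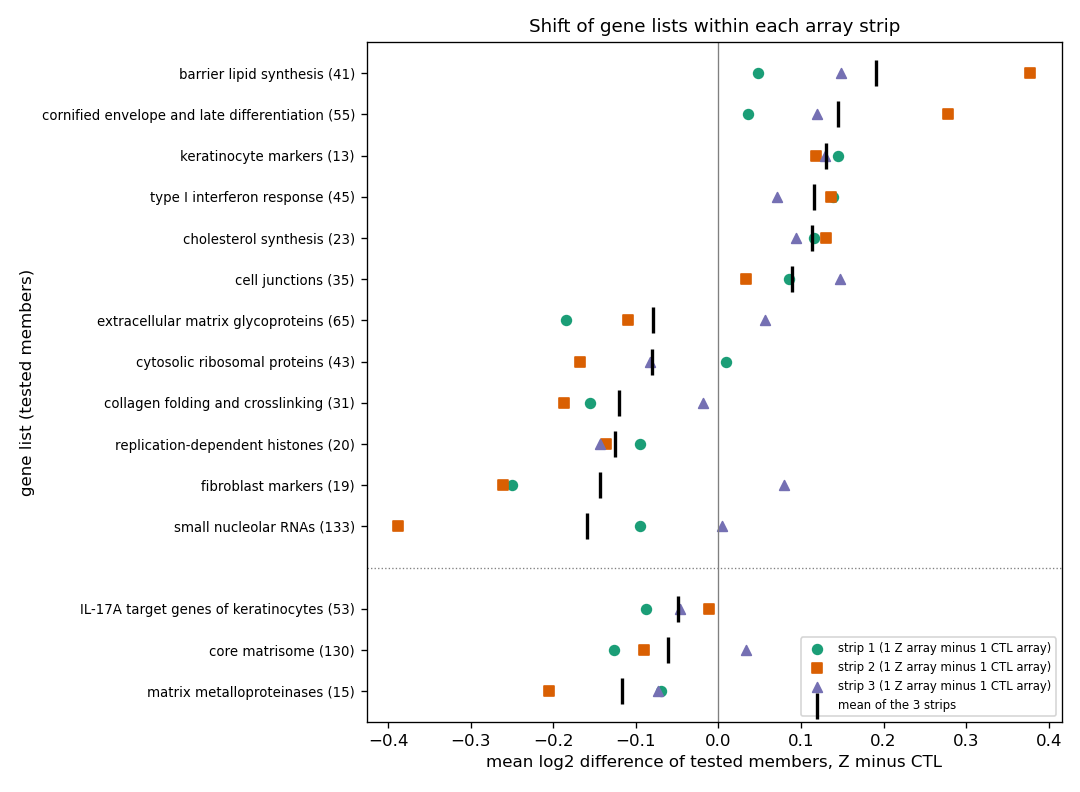
Mean log2 difference Z minus CTL over the tested members (x axis) of the 12 lists called by camera with its preset correlation and, below the dotted line, of the 3 lists named by the series title (y axis), with a point for the array pair of each strip and a black bar for the mean of the strips. Barrier lipid synthesis lies at 0.05, 0.38 and 0.15 and fibroblast markers at -0.25, -0.26 and 0.08 on strips 1, 2 and 3.

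Small nucleolar RNAs, which guide the modification of ribosomal RNA, fell in camera, 94 of 133 lower with a mean of -0.16 (limma adjusted p = 8.06e-05, adjusted p = 0.752 with an estimated correlation). SNORA72 differed by -1.32 (SE 0.35) and SNORA15, low at 2.53 in CTL, by 0.57 (SE 0.15), and members of a family may share probes. The mean was -0.10, -0.39 and 0.00 on strips 1, 2 and 3. It was -0.26 without CTL 3, -0.24 without Z 1 or without strip 3, -0.09 without Z 2 and -0.05 without strip 2, where the list was not called (limma adjusted p = 0.0613). Cytosolic ribosomal proteins, 30 of 43 lower, fell with a mean of -0.08 (limma adjusted p = 0.0303, adjusted p = 0.786 with an estimated correlation), with RPL35A at -0.28 and RPL27 at -0.32, and at 0.01, -0.17 and -0.08 on the 3 strips. Replication-dependent histones, 16 of 20 lower, fell with a mean of -0.13 (limma adjusted p = 0.0347, adjusted p = 0.752 with an estimated correlation), with H1-5 and H2BC14 both at -0.36, and at -0.10, -0.14 and -0.14 on the 3 strips. The ribosomal call was lost in limma without CTL 1, CTL 2, Z 2, Z 3, strip 2 or strip 3 (adjusted p from 0.0723 to 0.325, means from -0.15 without Z 1 to -0.04 without strip 2). The histone call was lost without CTL 1, CTL 3, Z 1, Z 2 or any strip and above the 75th percentile of level (adjusted p from 0.0606 to 0.136). Cell cycle genes (33 of 56 higher, PCNA -0.40, CCNA2 -0.40) were not called (limma adjusted p = 0.821), and their mean of 0.0012 was above 0 while camera placed them lower.

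In all, camera with the preset correlation called 12 of 40 lists, 6 higher and 6 lower in Z. With an estimated correlation camera called 0. In simulation that setting called a list shifted by 0.15 in 0 of 20 runs, so it cannot tell a shift of that size from none. Fry called 0 (smallest adjusted p 0.0541 in limma, for keratinocyte markers). With the strip as a block and the preset correlation, camera called 13. In 200 simulated runs without an effect, whose 40 lists each had the size and estimated correlation of a real list, the preset correlation called 7.7 lists on average and 19 at most. At least 12 were called in 19 of these runs. The simulated lists shared no members, unlike the real ones, so that share may understate how often 12 calls arise without an effect. The IL-17A targets were the 1 list of 40 in which any member passed limma adjusted over the list alone, and over all genes 0 members of any list passed. Adjustment within a list does not correct for the 40 lists, so 1 such list can arise without an effect.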

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

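All of these settings were fixed before the data were examined. Limma called 0 genes under each setting except without CTL replicate 3, where it called 1 (smallest adjusted p 0.0244). Arrays left out thus gave 0 to 1. Of 14868 genes, 1225 (8.24%) had an unadjusted p under 0.05 with all arrays, 1926 with the replicate block and 2007 with a random strip effect. Of all 53617 probe sets, 3402 (6.35%) did with all arrays. Camera called 12 lists, and 0 with an estimated correlation and 0 by fry, which test against a larger variance of the list mean or against no other genes. It called 2 to 18 lists when arrays were left out, which also left fewer samples: 5 without CTL 1, 6 without CTL 2, 6 without Z 1, 5 without strip 1 and 2 without strip 2, of which 0 were among the 12. Without Z 2 it called 18, 7 higher and 11 lower. The replicate block called 13 lists, the 12 and cytokines and chemokines, and changed no other call. Centring, quantile normalization again and the mean of probe sets each called the same 12. Above the 75th percentile of level it called 17, 6 higher and 11 lower, without a filter 13 and on ranks 11. The core matrisome kept its direction and ranged from -0.13 to -0.023 without arrays, and was called above the 75th percentile of level (-0.079, limma adjusted p = 0.0111; range over settings 0.00241 to 0.793). The MMP list was called there only (-0.24, limma adjusted p = 0.0151; range 0.0151 to 0.752). IL-17A targets stayed uncalled under each setting. For these changes the cause was not tested. Among named genes 929 comparisons kept direction and side of the threshold and 7 changed sign, all with arrays left out: COL1A1 (-0.010 to 0.135), MMP2 (-0.070 to 0.042), S100A7 (-0.071 to 0.043) and S100A8 (-0.030 to 0.057). Among the other lists, 533 comparisons stayed, 19 gained and 81 lost the call, and 29 changed sign. With arrays left out, means ranged from -0.153 to 0.070 for EGFR ligands and immediate early genes, -0.146 to 0.10 for NF-kB, -0.0063 to 0.069 for NRF2, -0.056 to 0.033 for cell cycle, -0.107 to 0.0052 for collagens, -0.104 to 0.030 for hypoxia, -0.303 to 0.015 for the late cornified envelope cluster, -0.256 to 0.014 for metallothioneins, -0.113 to 0.014 for oxidative phosphorylation, -0.064 to 0.068 for nerve and muscle markers and -0.101 to 0.028 for the unfolded protein response. Without a filter TRP channels were at 0.013 and nerve and muscle markers at 0.0065. Cell cycle genes were at -0.023 above the 75th percentile, -0.0028 after centring and -0.012 after quantile normalization again. The cause was not tested. The table has no background level, so signal over background could not be set against these values.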

Other observations

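Genes of xenobiotic metabolism were higher in Z for 13 of 21 tested members. They held the cytochrome P450 genes CYP2S1 at 0.64 (SE 0.15) and CYP2J2, low at 2.59 in CTL, at 0.76 (SE 0.22). The list was not called (mean 0.14, limma adjusted p = 0.105). That mean was 0.05 without the filter on level, 0.10 without Z 2 and 0.19 without Z 3. NRF2 target genes, which respond to electrophiles and oxidants, went both ways (20 of 38 higher, limma adjusted p = 0.672), with CES1 at 0.35 and CD36 at 0.32. Antioxidant enzymes held GPX7 at -0.76 (SE 0.22) and GSTM2 at -0.43, and their mean of -0.07 and median of 0.0029 had opposite signs (limma adjusted p = 0.144), and they were called above the 75th percentile of level (-0.10, adjusted p = 0.0225), against an adjusted p of 0.752 with all arrays and an estimated correlation. Their mean was -0.04 without Z 3. TRP channels, the family that pungent compounds activate in sensory neurons, were lower for 7 of 12 genes and had TRPC1 at -0.33 and TRPV2 at -0.29 (limma adjusted p = 0.447), with means from -0.08 without strip 1 to -0.03 without strip 3.

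Of the stress lists none was called in limma with all arrays: heat shock proteins (13 of 20 lower, HSPA6 -0.45, CHORDC1 0.58, adjusted p = 0.284), the unfolded protein response (21 of 37 lower, SYVN1 0.45, PHGDH 0.34, adjusted p = 0.568), p53 targets (16 of 29 lower, mean -0.06, POLH 0.48, SPATA18 0.41, adjusted p = 0.58), hypoxia and glycolysis (24 of 38 lower, KDM3A 0.34, TPI1 -0.29, adjusted p = 0.534) and metallothioneins (9 of 13 lower, MT3 -0.73, MT4 0.43, adjusted p = 0.568). Without CTL 3 the means of heat shock proteins and p53 targets were -0.14 and -0.15, while the former was -0.01 without Z 3 and the latter -0.0084 without CTL 1. EGFR ligands and immediate early genes (18 of 36 lower, EGR1 0.68, IER3 -0.62, adjusted p = 0.439 in limma) and oxidative phosphorylation (29 of 45 lower, NDUFB6 -0.40, NDUFA6 -0.35, adjusted p = 0.086 in limma) were not called with all arrays. The first was called without Z 2 (-0.15, limma adjusted p = 0.0232), and the second without Z 1 (-0.11, adjusted p = 0.0131), without strip 1 (-0.11, adjusted p = 0.0298) and above the 75th percentile of level (-0.08, adjusted p = 0.0151). Their adjusted p in limma was 0.856 and 0.786 with all arrays and an estimated correlation, and the mean of the first was 0.07 without Z 3 and of the second 0.01 without strip 2.

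The tests of the fibroblast share, of strip 2 and of the Z array on strip 2 were chosen after related values had been seen. With camera's preset correlation, the called epidermal lists were higher and the called fibroblast and matrix lists lower in Z. Some of these lists share members, so their shifts are not separate observations. DSC3 and CDH1, for example, are in both keratinocyte markers and cell junctions, and FBLN2 is in both fibroblast markers and matrix glycoproteins. The late cornified envelope cluster, not called, was at -0.11. An estimated correlation left 0 lists called. Without the arrays of strip 2, the mean of cell junctions went from 0.09 (bootstrap interval over members 0.03 to 0.14) to 0.12 (0.06 to 0.18). That of keratinocyte markers went from 0.13 (0.05 to 0.21) to 0.14 (0.05 to 0.22). Those calls ended with fewer arrays and not with a smaller mean, which argues against strip 2 alone as their source. By medians over members, however, strip 2 was the largest in both lists. Medians on strips 1, 2 and 3 were 0.12, 0.22 and 0.16 for cell junctions and 0.13, 0.16 and 0.11 for keratinocyte markers. Strip 2 alone is not excluded, because these lists were picked by that trait of the mean and the intervals resample genes, not tissues. Of the other 5 lists 0 passed without strip 2, which met the first criterion for strip 2 alone, though fewer arrays remained. A bound added after that result asked for a mean over strips 1 and 3 under 0.25 of that on strip 2. None met it, but barrier lipids (0.259) and the cornified envelope (0.279) came close, so strip 2 alone stays open. Barrier lipids went from 0.19 (0.13 to 0.25) to 0.10 (0.04 to 0.16) and the cornified envelope from 0.14 (0.07 to 0.22) to 0.08 (-0.0025 to 0.15). Collagen folding went from -0.12 (-0.18 to -0.06) to -0.09 (-0.15 to -0.02) and fibroblast markers from -0.14 (-0.23 to -0.05) to -0.09 (-0.16 to -0.01). Matrix glycoproteins went from -0.08 (-0.13 to -0.03) to -0.06 (-0.12 to -0.01). Collagen folding, fibroblast markers and matrix glycoproteins were also low on strip 1 (-0.16, -0.25 and -0.18, against -0.19, -0.26 and -0.11 on strip 2). That speaks against strip 2 alone, but 1 pair of arrays does not exclude it, with strip 3 at -0.02, 0.08 and 0.06. A lower share of fibroblast RNA in the Z tissues may also explain part of the pattern. A share of 0.737 of the 19 tested markers was lower (median -0.13, bootstrap interval -0.25 to -0.02), with an interquartile range of 0.25. The 6 brightest, chosen after values were seen, went both ways (LUM -0.23, COL1A1 0.06, COL1A2 -0.02, DPT -0.13, FAP -0.30 and FBN1 0.14). Their SEs ran from 0.13 for COL1A1 to 0.18 for DPT. Measurement error alone can give such a spread, so it does not decide on a lower share. The vehicle, 0.25% DMSO by dilution, cannot be told apart from zingerone because no array received it alone, and an effect of zingerone on the epidermis or dermis stays open beside these.

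Small nucleolar RNAs were lower in Z, and a lower yield of small RNA, which silica columns retain poorly, may account for it. The median of 192 microRNA and other small RNA features above the 75th percentile was -0.0086 (bootstrap interval -0.06 to 0.05), which met neither bound set beforehand. Of these, 122 microRNA features had a median of 0.06 (bootstrap interval -7e-04 to 0.10) and 70 others one of -0.15 (-0.26 to -0.07), so the classes went apart. The bounds were set for both classes together, and the fall of the 70 others leaves a lower yield open. Without the Z array on strip 2, the array alone as a source, the median was -0.10 (bootstrap interval -0.14 to -0.03) with limma adjusted p = 0.0219, which neither excludes nor meets that explanation: strip 1, with a median of -0.09, speaks against it, and strip 3, at 0.0043, does not. A response to zingerone is not separated from these.

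The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. As many genes at an unadjusted p under 0.05 came from 2 splits, with 1225 in the real one and 1910 in the highest other, which set CTL 1, CTL 2 and Z 1 against the rest and so parted strip 1 from strip 3. As many called lists came from 1 split (12, highest other 11). A camera p as small came from 3 splits for the core matrisome (0.023, smallest other 4.97e-05), 1 for the MMPs (0.0478, smallest other 0.0736) and 4 for IL-17A targets (0.625, smallest other 0.298). Among the 4 splits that part all 3 strips, with the strip as a block, the real one gave 1926 genes at an unadjusted p under 0.05 and 13 lists, and the others gave 463, 343 and 603 genes and 9, 7 and 7 lists.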
